A study of Mus musculus with 3 samples.

How the data were processed

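The study measured spatial gene expression in 3 sections labelled cerebellum, 1 each from a home cage, a fear conditioned and an auditory retrieval mouse (male, 6 to 8 weeks old per the labels' protocols). Per the labels' protocols, conditioning used 5 pairings of a 30 s tone of 2800 Hz with a 2 s foot shock of 0.5 mA, retrieval used 2 or 3 tones in a different chamber 24 h after conditioning, and tissue was taken 60 min after either. The deposited matrices hold raw UMI counts of 32285 genes per barcoded spot, and Space Ranger 1.3.1 with the mm10 build is named as the processing tool per the submitters' processing notes. No normalization had been applied to the deposited counts: all values were whole numbers and the totals differed between sections. The files pair each gene identifier with a symbol, and these symbols were used.

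The matrices held 3245 home cage, 3349 fear conditioned and 3542 auditory retrieval barcodes. In the home cage section 23 barcodes of the matrix were not flagged as lying over tissue by the deposited positions and were left out. Spots with fewer than 500 UMIs were left out, 252, 368 and 217 in the same order. No doublet caller was run and no cell-type makeup was estimated, since a spot can hold several cells. GC content was not checked, because no genome sequence was at hand.

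Regions were found from the spots of all 3 sections together. Counts were log-normalised and scaled within each section, 2000 variable genes gave 30 principal components, and a graph of 15 neighbours was clustered with the Leiden method at resolution 0.8. Immediate early, glucocorticoid, heat shock, circadian, mitochondrial, haemoglobin and sex-linked genes were left out of the features. Of 17 clusters, 14 had at least 50 spots in every section and were compared. The other 3 were left out, among them the Acta2/Tagln cluster (28, 37 and 47 spots in home cage, fear conditioned and auditory retrieval) and the Ccdc153/Tmem212 cluster (27, 23 and 38). A region is called by the 2 genes with the highest ratio of CPM inside to outside it, and its share of spots carries an exact Clopper-Pearson interval.

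Each of the 3 comparisons (fear conditioned against home cage, auditory retrieval against home cage, auditory retrieval against fear conditioned) was a description of 2 sections. Counts were summed per region and scaled to CPM (counts relative to the total UMIs), and values over all regions are means of the 14 regional CPM with equal weight. Log2 folds were taken after adding 0.5 counts per region, and printed folds are ratios of CPM without it. Intervals are at the 95% level. They are exact Poisson for the CPM of a region, conditional binomial for folds within a region, and gamma for mean CPM over regions. Those of folds over all regions and of list medians come from 1000 Poisson resamplings. The resampled fold intervals are placed around the log2 fold with added counts. At low counts the printed fold can therefore lie near an end of its interval. All of them cover counting error only, not variation between animals, sections or libraries. A gene counted as higher or lower by the size rule when its CPM differed by at least 1.5-fold, the 2 intervals did not overlap, and it had at least 50 counts in the higher section. For each gene list with members of at least 10 counts, the median log2 fold was placed as a percentile among 10000 random lists of the same size matched on mean expression, drawn from 200 genes of nearest expression per member; a list stood outside the central range below percentile 2.5 or above 97.5.

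The genes named followed a rule fixed before the data were examined. In each comparison and region the 3 highest and 3 lowest genes by CPM fold were picked among genes with at least 50 counts in the higher and 10 in the lower section and separate intervals, leaving out mitochondrial, haemoglobin, ribosomal protein, sex-linked and unnamed genes. Fos, Junb, Egr1, Nr4a1, Arc, Npas4, Bdnf and Homer1 were named whatever their value, and from each preset list the 2 to 4 members with the largest fold and at least 50 counts. The text names fewer list members than this rule set: none for 6 lists in retrieval against home cage and 9 in retrieval against fear conditioned, and 1 for some others. The rule picked 84 genes by region in each comparison (54, 64 and 72 distinct genes), and the choice to name from these only the picks of the Spp1/Cd24a region and some genes picked in 2 or more regions was made after their number was seen. Of the 8 always-named genes, the text gives single regions other than Spp1/Cd24a only for Fos, Junb and Egr1, and only in the Pcp2/Rgs8, Tnfaip6/Ppp1r14a and Ttr/Kl regions, chosen after their values were seen. Some genes, and regions called by them, are not reported here, although they were kept in the sums, list medians and counts. The 16 preset lists were rapid immediate early, delayed activity-dependent, glucocorticoid-responsive, heat shock and unfolded protein response, circadian, parallel fibre to Purkinje cell plasticity, glutamate receptor, GABA and glycine, presynaptic vesicle, ion channel, extracellular matrix, oxidative phosphorylation, neuropeptide and receptor, reactive glia, zebrin-positive and zebrin-negative genes. The 16 marker lists covered granule layer, Purkinje and molecular layer, white matter, deep nuclei and brainstem neurons, Bergmann glia and astrocytes, interneurons and Golgi cells, unipolar brush cells, meninges, endothelium, choroid plexus, ependyma, microglia, oligodendrocyte precursors, blood, forebrain and midbrain neurons, and nuclear-retained transcripts.

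Alternatives fixed before the data were examined were a minimum of 1000 UMIs per spot or none, TMM factors, totals without mitochondrial, haemoglobin and ribosomal protein genes, Leiden resolutions of 0.4 and 1.5, regions by marker score, spots thinned to 2000 UMIs (which left out 218, 202 and 352 shallower spots), the left or right side of array column 64 alone (whether these are the same anatomical side in the 3 sections is not given in the sources used here), whole sections without regions, 2 counts added, list members with 50 or more counts, a 2-fold rule, 200 counts in the higher section, and a minimum of 1 count. Restriction to 6 cerebellar regions was added after seeing that the sections held much tissue outside the cerebellum.

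The size rule, the CPM intervals and the list percentiles were tested on simulated counts over 21529 genes, with 50 genes changed by each of 4 folds. Both sections were drawn as Poisson counts from the same mean profile, pooled over the 3 real sections, with the real totals. The unchanged lists were random genes. Variation between libraries and lists of genes that vary together were thus not covered, and false calls in the real data can be more frequent. For fear conditioned against home cage the rule recovered 54% of genes changed 1.5-fold, 100% of those changed 2-fold and 3-fold and 98% of those changed 0.5-fold, and called 10 unchanged genes. For auditory retrieval against home cage these were 56%, 100%, 100%, 100% and 10 genes, and for auditory retrieval against fear conditioned 52%, 100%, 100%, 96% and 5 genes. The CPM intervals of the second section named in each comparison held the true CPM for 95.7%, 95.3% and 95.5% of 12162 genes. The fold intervals were not checked. Of 100 unchanged lists, 7, 3 and 4 fell outside the central range. Positions of Fos, Junb and Egr1 came from a RefSeq annotation of the GRCm38 assembly, which is the assembly of mm10. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3.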

Results

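Spatial gene expression was measured with 10x Visium, which captures RNA on a grid of barcoded spots, in 3 coronal sections labelled cerebellum from male C57BL/6N mice. The home cage section came from an undisturbed mouse, and the fear conditioned section from a mouse taken 60 min after 5 pairings of a tone with a foot shock. The auditory retrieval section came from a mouse taken 60 min after a tone test held 24 h after pairing. Each group held 1 section, so no difference between groups had a replicate check, no p-value was computed, and every interval below covers counting error only. After filtering, 2970 home cage, 2981 fear conditioned and 3325 auditory retrieval spots were used, with 27551609, 30470390 and 27345037 UMIs. Median UMIs per spot were 8121 in the home cage, 8056 in the fear conditioned and 7095 in the auditory retrieval section. Depth was least even in the fear conditioned section, with medians of 13101 on the left and 5341 on the right side of the array. These were 9313.5 and 7006.5 in home cage, and 7434.5 and 6683 in auditory retrieval. Mitochondrial transcripts made up 11%, 8.65% and 12.4% of the UMIs in the same order, and haemoglobin transcripts 0.0172%, 0.00417% and 0.0322%.

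Clustering of the spots of all 3 sections, with immediate early and stress genes kept out of the features, gave 14 regions with at least 50 spots in every section. Each region was called by its 2 leading genes. The Pcp2/Rgs8 region was led by Purkinje cell genes and lay in the cerebellar cortex, and the Rnf112/Grm4 region carried granule layer markers. The Spp1/Cd24a region formed a band on both sides of the midline beneath the cerebellar cortex, and 5 of the deep nuclei and brainstem neuron markers were among its top 50 genes. It held 10.1% of the home cage spots (exact binomial interval 9.07 to 11.3), 9.36% of the fear conditioned spots (8.34 to 10.5) and 6.59% of the auditory retrieval spots (5.77 to 7.48). The Calca/Tac1 region, led also by the serotonergic genes Tph2 and Slc6a4 and lying in the lower part of each section, was close in share at 14.8%, 14.7% and 14%. The Kit/Sla region of the cerebellar cortex took 5.96% of home cage spots against 13.3% and 13.5% in the fear conditioned and auditory retrieval sections. With coarser clusters, at resolution 0.4, the shares were 17.0%, 24.4% and 20.2%, a smaller contrast. When every spot over tissue was kept they were 2.79%, 6.33% and 8.72%, and the 2 behaviour sections were no longer close. Because the sections differed in these shares, expression was compared within regions or as a mean over the 14 regions with equal weight.

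**Figure D1:**
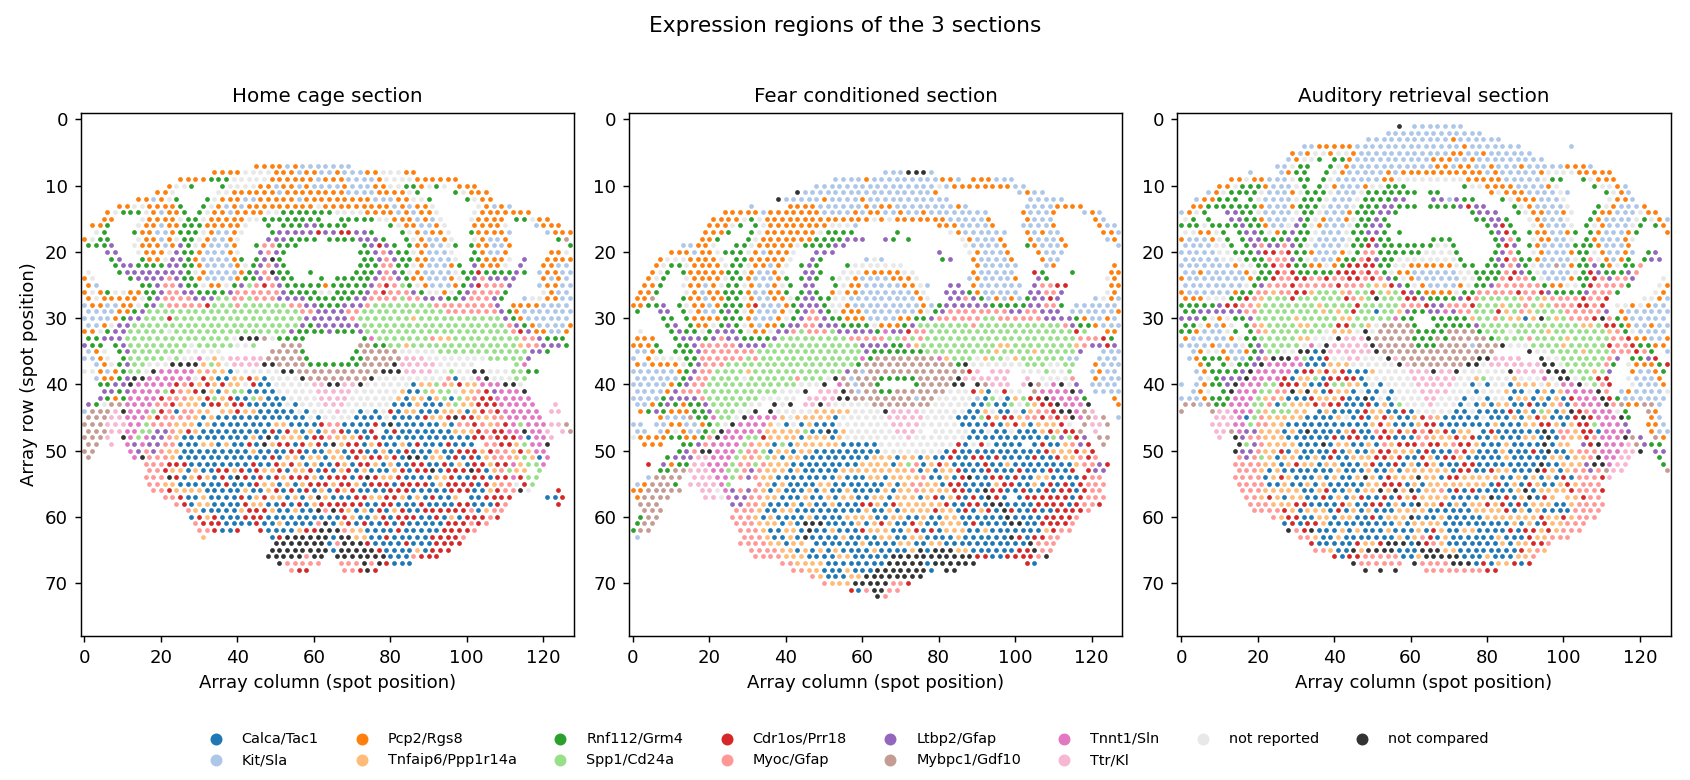
Spots of the 3 sections by array column (x) and array row (y), coloured by expression region and named by the 2 leading genes of each; pale grey spots belong to regions not reported here and black spots belong to clusters too small to compare. The Spp1/Cd24a band beneath the cerebellar cortex held 301 spots in the home cage, 279 in the fear conditioned and 219 in the auditory retrieval section.

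Fear conditioning was compared with home cage to ask which genes and regions differed 60 min after tone and shock. The clearest difference lay in the Spp1/Cd24a region, where the activity-induced transcription factor genes Fos, Junb and Egr1 were the 3 highest in the fear conditioned section relative to home cage among genes with at least 50 counts in the higher and 10 in the lower section. The 3 highest and 3 lowest genes below are all ranked among such genes with separate intervals. Fos (ENSMUSG00000021250) stood at 85.1 CPM (counts scaled to the total UMIs of the region, 287 counts) against 7.20 CPM (27 counts), an 11.8-fold difference with a counting interval of 7.95 to 18.2. Junb (ENSMUSG00000052837) stood at 50.7 CPM against 7.20 CPM, 7.04-fold higher (4.67 to 11), and Egr1 (ENSMUSG00000038418) at 31.1 CPM against 5.6 CPM, 5.56-fold higher (3.46 to 9.35). In the mm10 build these protein-coding genes lie on chromosome 12 at 85473890 to 85477274 (Fos), chromosome 8 at 84976909 to 84978748 (Junb) and chromosome 18 at 34861207 to 34864956 (Egr1). Npas4, a neuronal activity-dependent transcription factor gene, had 34 counts against 2, a ratio of 18.9 with a wide interval of 4.85 to 162, and Arc, which acts at synapses, was 1.68-fold higher (1.23 to 2.28). Both sides of the section showed the Fos difference, at 84.2 CPM on the left and 87.6 CPM on the right of the fear conditioned section against 6.94 and 7.55 CPM in home cage. Nr4a1 was at 1.52-fold (0.946 to 2.45), Bdnf at 0.855-fold (0.336 to 2.11) and Homer1 at 0.992-fold (0.684 to 1.44) in the same region, none of them separable from equal levels at this depth. Hox genes of paralog groups 4 and 5, which mark position along the hindbrain, had a median log2 fold of 1.43 over all regions in this comparison, with 7 of 7 higher.

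**Figure D2:**
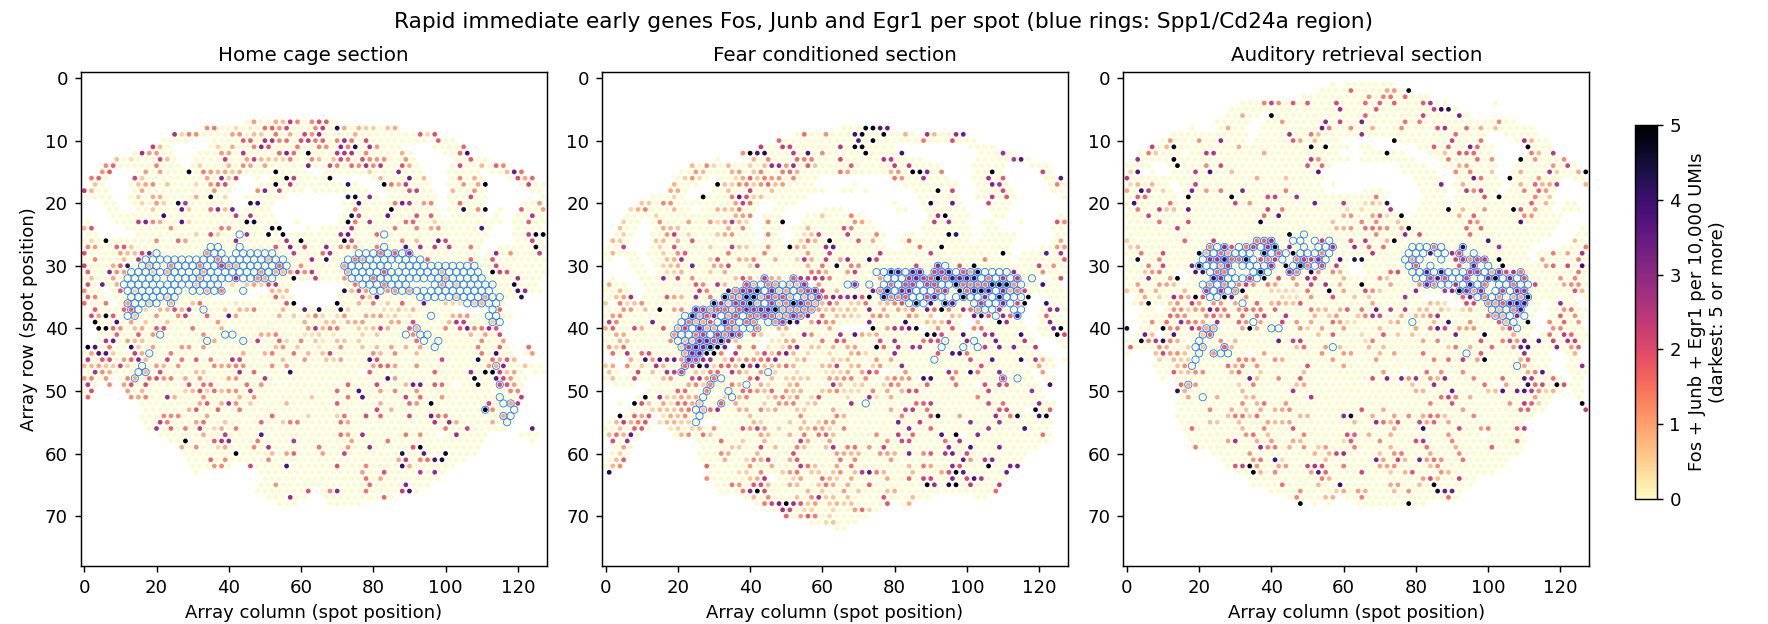
Summed Fos, Junb and Egr1 UMIs per 10,000 UMIs of each spot (colour, capped at 5), by array column (x) and array row (y), with the spots of the Spp1/Cd24a region ringed in blue. Dark spots fill the ringed band in the fear conditioned section, where Fos was at 85.1 CPM, and are scarce in the home cage band, where Fos was at 7.20 CPM.

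Outside that band the rapid immediate early genes did not move together. In the Pcp2/Rgs8 region Fos was lower in the fear conditioned section, at 12.9 CPM against 30.2 CPM, whereas Junb was higher, at 18.2 CPM against 10.4 CPM. Counting the band, Fos was higher in 6 and lower in 8 of the 14 regions, with separate CPM intervals in 3 and 2 of them. Junb was higher in 13 of 14 regions, with separate intervals in 3. Among the 28 measured members of the rapid immediate early list, 15 were higher over all regions, and the CPM intervals of 4 higher and 4 lower members did not overlap. The list's median log2 fold was 0.07 (interval -0.03 to 0.17), at percentile 54.7 of 10000 random lists matched on expression. It was 0.00 with TMM scaling, 0.21 on the left and 0.24 on the right side of the array alone, and its percentile reached 97.2 among the settings tried. By region it ranged from -0.56 in the Ltbp2/Gfap region (percentile 0) to 0.60 in the Cdr1os/Prr18 region (percentile 94.6), with 0.59 in the Spp1/Cd24a region (interval 0.27 to 0.92, percentile 100, 20 of 25 members higher). Over all regions Junb was 1.98-fold higher (1.67 to 2.32) and Npas4 1.79-fold (1.22 to 2.42). Nr4a3 stood at 0.533-fold (0.447 to 0.664) and Nr4a1 at 0.791-fold (0.686 to 0.915). Fos was at 1.09-fold (0.975 to 1.23), Egr1 at 1.16-fold, Arc at 1.22-fold, Bdnf at 0.999-fold and Homer1 at 1.08-fold.

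**Figure D3:**
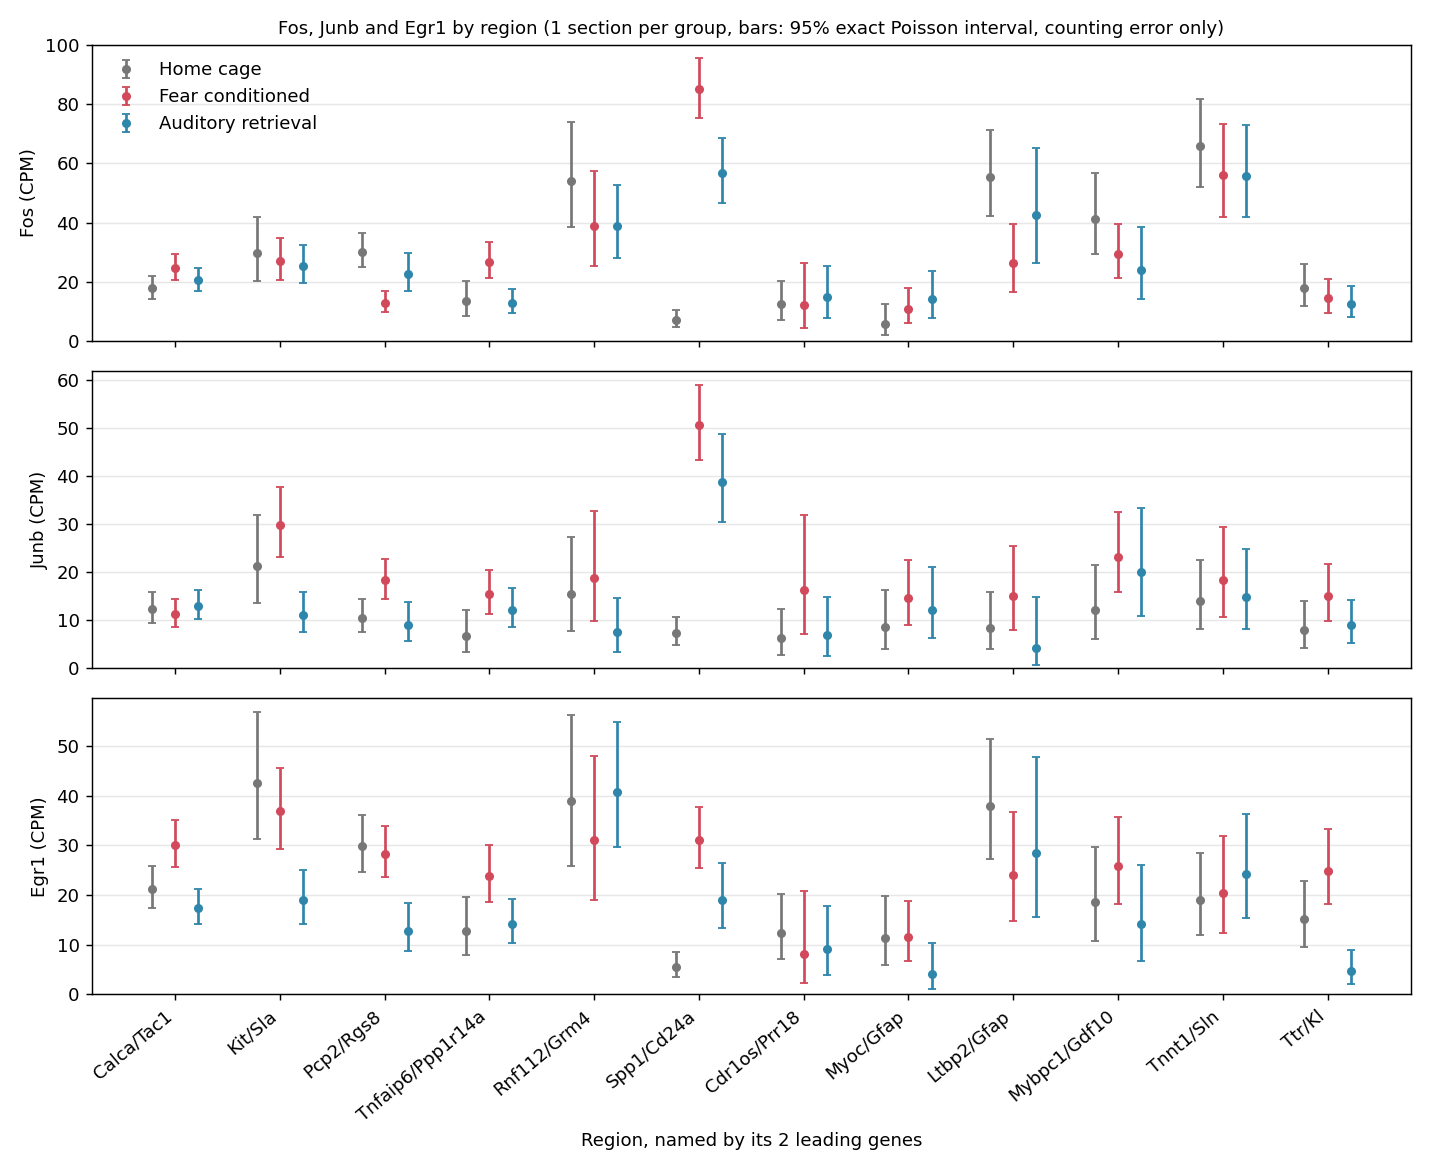
Fos, Junb and Egr1 in CPM (y) by region (x) for the home cage, fear conditioned and auditory retrieval sections; points are summed-count CPM of 1 section and bars are 95% exact Poisson intervals. In the Spp1/Cd24a region the Fos, Junb and Egr1 points of the fear conditioned section (85.1, 50.7 and 31.1 CPM) and of the auditory retrieval section (56.7, 38.7 and 19.1 CPM) lie above the home cage points (7.20, 7.20 and 5.6 CPM).

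Genes known to respond to glucocorticoid hormones were higher in the fear conditioned section. Of 23 measured members, 19 were higher over all regions and the intervals of 14 higher and 0 lower members were apart. The list had a median log2 fold of 0.30 (0.22 to 0.36, percentile 100) and a median above 0 in 14 of 14 regions. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, was 2.28-fold higher (1.93 to 2.61), and Pdk4, a kinase that restrains pyruvate oxidation, 2.08-fold (1.68 to 2.5). Also higher were Cdkn1a, a cell cycle inhibitor, 2.00-fold (1.75 to 2.23) and Plin4, a lipid droplet protein, 1.91-fold (1.62 to 2.21). Heat shock and unfolded protein response genes had a median of 0.15 (0.11 to 0.19, percentile 100), with 22 of 23 members higher. Among them were Sdf2l1 at 1.41-fold (1.24 to 1.59), Hspa1b at 1.38-fold (1.10 to 1.71) and Hspa1a at 1.3-fold (1.10 to 1.55). The marker lists for Bergmann glia and astrocytes and for endothelium stood at 0.13 (percentile 99.6) and 0.07 (percentile 70.2) in the same comparison. The mitochondrial share was lower in the fear conditioned section (8.65% against 11%), as were blood transcripts (median -1.77).

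Signalling genes of the parallel fibre to Purkinje cell synapse had a median of 0.16 (0.12 to 0.20, percentile 100), with 22 of 25 members higher. These included Camk2a at 1.37-fold (1.18 to 1.57) and Grip1 at 1.38-fold (1.03 to 1.77). Purkinje cell and molecular layer markers were higher alongside, with a median of 0.17 (0.15 to 0.19, percentile 100). Glutamate receptor genes had a median of 0.13 (percentile 99.4, 17 of 23 higher), with Grin3a at 1.42-fold (1.24 to 1.65) and Grm3 at 0.694-fold (0.516 to 1.03). Neuropeptide and receptor genes had a median of 0.23 (0.14 to 0.37, percentile 100, 16 of 19 higher), with Calca at 2.44-fold (1.93 to 2.88), Calcb at 3.12-fold (1.47 to 3.36), Cartpt at 2.03-fold (1.64 to 2.43) and Tac1 at 1.85-fold (1.60 to 2.08). Calca and Tac1 also led the region that carries their names. The higher neuropeptide values came from the same section as the higher Hox genes of groups 4 and 5 (median 1.43), so the position of the section is not separated from behaviour for this list. Reactive glia genes had a median of -0.08 (-0.19 to 0.01, percentile 0.22, 6 of 19 higher), with the antigen presentation gene Cd74 at 0.662-fold (0.558 to 0.814) and Serpina3n at 1.36-fold (1.13 to 1.61). Of 15 settings, counting the one used here, glucocorticoid and heat shock lists were outside the central 95% of random lists in 15, Purkinje synapse genes in 14 and neuropeptides in 13. Glutamate receptors were outside in 11 (lowest percentile 73.1) and reactive glia genes in 10 (highest 83.5), so the last 2 depended on the setting. The median log2 fold of all genes was 0.06 in this comparison, and -0.00 with TMM scaling. With TMM the list medians were 0.09 for heat shock genes, 0.09 for Purkinje synapse genes, 0.05 for glutamate receptors, -0.15 for reactive glia genes and 0.07 for Bergmann glia and astrocyte markers.

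The other preset lists lay inside the central 95% of random lists, and the shift of all genes was of the size of several of their medians. These were 0.07 for delayed activity-dependent genes (Inhba at 0.743-fold, Pcsk1 at 1.3-fold), 0.08 for GABA and glycine genes (Slc6a11 at 1.24-fold, Gad1 at 1.19-fold), 0.09 for ion channels (Hcn2 at 0.615-fold, Kcna1 at 0.646-fold). They were 0.11 for extracellular matrix genes (Hapln1 at 0.777-fold, Hapln2 at 1.25-fold), -0.02 for oxidative phosphorylation (Ndufa13 at 0.917-fold, Atp5e at 0.931-fold) and 0.14 for zebrin-positive Purkinje cell genes (Prkcd at 1.45-fold, Kctd12 at 1.24-fold). The medians of 0.04 for circadian genes (Dbp at 0.731-fold, Per2 at 1.19-fold), 0.06 for presynaptic vesicle genes (Stx1a at 1.47-fold, Syt1 at 1.15-fold) and 0.04 for zebrin-negative genes (Ebf2 at 0.820-fold) turned to -0.02, -0.00 and -0.01 under TMM scaling. Among markers of cell types, those of the granule layer (-0.06, percentile 0), meninges (-0.14, percentile 0), ependyma (-0.24, percentile 0) and blood (-1.77, percentile 0) were lower in the fear conditioned section. The granule layer markers (-0.10 with TMM scaling) had nearly equal summed CPM, with a log2 fold of 0.01. Nuclear-retained transcripts did not move together, with a median of 0.21 (percentile 99.8) but a mean of 0.03, 4 of 6 higher and Malat1 at 0.707-fold. White matter (-0.00), molecular layer interneuron and Golgi cell (0.12), choroid plexus (0.06), microglia (0.09), oligodendrocyte precursor (-0.02) and forebrain and midbrain neuron markers (0.17) lay inside the central range, as did deep nuclei and brainstem neuron markers (0.07) and unipolar brush cell markers (0.02). The last 2 turned to a negative sign under TMM scaling at -0.03 and -0.01.

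By the size rule of a 1.5-fold difference with separate counting intervals, 86 genes were higher and 53 lower in the fear conditioned section over all regions. With TMM scaling these were 66 and 67, and with totals that left out mitochondrial, haemoglobin and ribosomal protein genes 72 and 62, so that the share of higher genes moved from 61.9% to 49.6% with TMM. Several of the largest differences recurred across regions. Dapk3, which encodes a death-associated protein kinase, was 4.16-fold lower over all regions (3.41 to 4.82), and the translation elongation factor gene Eef1a2 was 2.22-fold lower (2.12 to 2.32) and Ano8 2.28-fold lower (2.01 to 2.54). In the Spp1/Cd24a region these were the 3 lowest genes, with Dapk3 4.86-fold lower (3.15 to 7.77), Eef1a2 2.80-fold lower (2.5 to 3.13) and Ano8 2.45-fold lower (1.77 to 3.45). The peptide transporter gene Slc15a2 was 3.33-fold higher (2.83 to 3.75) and was among the 3 highest genes in 5 regions. Npy was among the 3 highest genes in 3 regions, by 3.29-fold to 4.18-fold, and Cdr1os among the 3 lowest in 3 regions, by 2.22-fold to 4.85-fold.

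Auditory retrieval was compared with home cage to ask which genes and regions differed after the tone was met again a day after pairing. The Spp1/Cd24a region again carried the highest Fos and Junb relative to home cage. Fos was at 56.7 CPM (107 counts) against 7.20 CPM (27 counts), 7.88-fold higher (5.13 to 12.5), Junb at 38.7 CPM against 7.20 CPM, 5.38-fold higher (3.41 to 8.70), and Egr1 at 19.1 CPM against 5.6 CPM, 3.41-fold higher (1.94 to 6.14). Fos stood at 56.4 CPM on the left and 57.0 CPM on the right side of the retrieval section. In that region Arc was at 1.33-fold (0.91 to 1.94), Nr4a1 at 0.663-fold (0.302 to 1.34), Bdnf at 1.68-fold (0.682 to 4.07) and Homer1 at 1.04-fold, and Npas4 had 5 counts against 2, a ratio of 4.97 (0.814 to 52.2). Lars2, a mitochondrial leucyl-tRNA synthetase gene, was 2.33-fold higher (1.94 to 2.81) and followed Fos and Junb in the ranking, which the counts of Npas4 and Egr1 were too low to enter. The retrieval section also had the higher share of mitochondrial transcripts (12.4% against 11%), which is not separated from behaviour for Lars2. Because both comparisons used the same home cage section, the low Fos, Junb and Egr1 counts of that section entered both, and the resemblance of the 2 comparisons is not independent evidence.

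Elsewhere the rapid immediate early genes were mostly lower in the auditory retrieval section than in home cage. Over all regions 9 of 28 members were higher, the intervals of 1 higher and 7 lower members were apart, and the list's median was -0.30 (-0.43 to -0.16, percentile 0). That median was -0.03 when every spot over tissue was kept, -0.13 with finer regions and -0.14 when 2 counts were added. The list lay below the central range in 11 of 15 settings and reached percentile 77.7 in the others. Nr4a3 stood at 0.465-fold (0.377 to 0.607), Nr4a2 at 0.583-fold (0.472 to 0.730), Ccn1 at 0.566-fold (0.431 to 0.856) and Klf2 at 0.631-fold (0.565 to 0.716). Junb was 1.34-fold higher over all regions (1.11 to 1.60), while Egr1 was at 0.780-fold (0.673 to 0.915), Nr4a1 at 0.692-fold (0.592 to 0.819), Fos at 1.04-fold, Arc at 0.987-fold, Npas4 at 1.06-fold, Bdnf at 0.887-fold and Homer1 at 0.905-fold. Nr4a3 and Nr4a1 were lower, and Junb higher, than home cage in the fear conditioned section too. The home cage section is thus not separated from behaviour for these genes. By region the list's median was above 0 in 2 of 14 regions, at 0.25 in the Spp1/Cd24a region (-0.07 to 0.53, percentile 99.8) and 0.08 in the Cdr1os/Prr18 region. It was -0.80 in the Rnf112/Grm4 region, -0.72 in the Kit/Sla region and -0.42 in the Pcp2/Rgs8 region.

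Heat shock and unfolded protein response genes stood apart in the auditory retrieval section, with a median of 0.28 (0.24 to 0.33, percentile 100), 21 of 23 members higher and 18 of them with separate intervals. The list had a median above 0 in 14 of 14 regions. The same section had a higher mitochondrial share (12.4% against 11%), more blood transcripts (median 1.27) and lower nuclear-retained transcripts (-0.35), and the design does not separate the state of the tissue from retrieval, for these genes or for the rapid immediate early list. Sdf2l1, an endoplasmic reticulum chaperone component, was 2.07-fold higher (1.82 to 2.31), the inducible chaperone gene Hspa1b 2.05-fold (1.61 to 2.47), Manf 1.73-fold (1.65 to 1.83) and Hspa1a 1.62-fold (1.37 to 1.89). Glucocorticoid-responsive genes had a median of 0.14 (0.06 to 0.21, percentile 100) with 13 of 23 members higher and medians above 0 in 8 of 14 regions, and the median turned to -0.09 when every spot over tissue was kept. The summed CPM of the list went the other way, at 4898 against 5720 (log2 -0.22). Cdkn1a was 1.69-fold higher (1.48 to 1.89), Pdk4 1.61-fold (1.25 to 1.99) and Fkbp5 1.57-fold (1.32 to 1.87), while Ddit4 was at 0.749-fold (0.692 to 0.816). Neuropeptide and receptor genes had a median of 0.12 (-0.01 to 0.25, percentile 99.97) but did not rise as a list, with 11 of 19 higher and a mean log2 fold of 0.00. Among them were Calca at 0.414-fold (0.336 to 0.640) and Vip at 0.632-fold (0.509 to 0.891). Ion channel genes had a median of -0.12 (-0.17 to -0.06, percentile 1.52) with 5 of 24 higher, and of -0.06 with TMM scaling. The median of all genes in this comparison was -0.07, and 0.00 with TMM. The pacemaker channel gene Hcn2 stood at 0.641-fold (0.614 to 0.667) and the P/Q-type calcium channel gene Cacna1a at 0.689-fold (0.648 to 0.733). Hcn2, Sdf2l1, Hspa1b, Hspa1a, Cdkn1a, Pdk4 and Fkbp5 differed from home cage in the same direction in the fear conditioned section. The home cage section is thus not separated from behaviour for these genes.

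Inside the central range of random lists were delayed activity-dependent genes at -0.08 (Dusp5 at 0.777-fold, Plk2 at 0.796-fold), circadian genes at -0.11 (Npas2 at 0.762-fold, Dbp at 0.796-fold). So were glutamate receptors at -0.07 (Grm3 at 0.673-fold, Grik2 at 0.755-fold), presynaptic vesicle genes at -0.07 (Cplx2 at 0.730-fold, Slc17a7 at 0.802-fold) and zebrin-positive genes at 0.09 (Prkcd at 1.20-fold, Kctd12 at 1.18-fold). Dbp, Grm3, Prkcd and Kctd12 went the same way against home cage in the fear conditioned section. A further 6 lists changed sign under TMM scaling, with the TMM value after each main one. They were parallel fibre to Purkinje cell genes (-0.02, then 0.05), GABA and glycine genes (-0.05, then 0.00), extracellular matrix genes (-0.06, then 0.02), oxidative phosphorylation genes (-0.04, then 0.04), reactive glia genes (-0.06, then 0.06) and zebrin-negative genes (-0.02, then 0.05). Markers of the granule layer (-0.20, percentile 0), endothelium (-0.21, percentile 0.58), ependyma (-0.23, percentile 1.65) and microglia (-0.23, percentile 0.17) and nuclear-retained transcripts (-0.35, percentile 0) were lower in the auditory retrieval section, and blood transcripts were higher (1.27, percentile 100). With TMM scaling the endothelium, ependyma and microglia medians were -0.13, -0.13 and -0.15. The remaining marker lists lay inside the central range, at 0.05 for Purkinje and molecular layer, -0.09 for deep nuclei and brainstem neurons, 0.02 for Bergmann glia and astrocytes, 0.03 for unipolar brush cells, -0.14 for oligodendrocyte precursors and -0.10 for forebrain and midbrain neurons. The values were -0.07 for white matter, -0.06 for interneurons, -0.08 for meninges and -0.07 for choroid plexus, and these 4 turned positive under TMM scaling.

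The size rule gave 41 higher and 109 lower genes in the auditory retrieval section against home cage, or 57 and 59 with TMM scaling, moving the share of higher genes from 27.3% to 49.1%. Dapk3 was 4.78-fold lower over all regions (3.83 to 5.59), Eef1a2 2.59-fold lower (2.47 to 2.71) and Ano8 2.41-fold lower (2.09 to 2.70). All 3 genes were lower than home cage in 14 of 14 regions of both behaviour sections, which stood closer to each other, at 0.869-fold, 0.859-fold and 0.946-fold for retrieval over fear conditioned. A property of the 1 home cage mouse, section or library is thus not separated from behaviour for these genes. In the Spp1/Cd24a region the 3 lowest genes were Dapk3 at 5.66-fold lower (3.14 to 11.2), Phf2 at 3.57-fold lower (1.89 to 7.44) and Ankfy1 at 3.22-fold lower (1.92 to 5.74). The tRNA and RNA modification gene Cdk5rap1 was 1.99-fold higher over all regions (1.56 to 2.43). It was also 4.31-fold higher than home cage in the Pcp2/Rgs8 region of the fear conditioned section. The home cage section is thus not separated from behaviour for Cdk5rap1 either.

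Auditory retrieval was set against fear conditioning to place the 2 behaviour sections beside each other. Fos, Junb and Egr1 were lower in the Spp1/Cd24a region of the retrieval section than in the fear conditioned one, at 0.667-fold (0.529 to 0.835), 0.763-fold (0.572 to 1.01) and 0.613-fold (0.408 to 0.903). The CPM intervals overlapped for Junb and Egr1. By the size rule 35 genes were higher and 491 lower in that region, and the median log2 fold of all genes there was -0.13. The single-gene folds are not corrected for that shift. The rapid immediate early list had a median of -0.60 in the region, at percentile 0.13 of random lists. Nr4a1 was at 0.437-fold (0.204 to 0.858) and Arc at 0.797-fold in that region, Npas4 at 0.263-fold (0.0803 to 0.676), Bdnf at 1.97-fold (0.758 to 5.17) and Homer1 at 1.05-fold. The 3 highest genes there were Lars2 at 2.63-fold (2.15 to 3.21), the neurotensin gene Nts at 2.30-fold (1.51 to 3.53) and Cdr1os at 2.18-fold (1.81 to 2.62). The 3 lowest were Gdf10 at 4.99-fold lower (2.81 to 9.65), Phf2 at 4.37-fold lower (2.33 to 9.08) and Slc1a6 at 4.23-fold lower (2.42 to 8.01). Gdf10 and Slc1a6 are Bergmann glia and Purkinje cell genes that also led the Mybpc1/Gdf10 region. The makeup of the region's spots and the state of the tissue are thus not separated from behaviour for single genes there.

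The median log2 fold of all genes in this comparison was -0.14, and -0.00 with TMM scaling, so list medians are given relative to that of all genes. Relative to it, rapid immediate early genes stood at -0.17 (median -0.31, interval -0.42 to -0.20, percentile 0.09, 5 of 28 higher), with Fosb at 0.497-fold (0.392 to 0.799), Zfp36 at 0.569-fold (0.451 to 0.739) and Dusp1 at 0.629-fold (0.574 to 0.691). Over all regions Junb was at 0.676-fold (0.579 to 0.794), Egr1 at 0.673-fold (0.581 to 0.780), Npas4 at 0.595-fold (0.431 to 0.900), Fos at 0.953-fold, Nr4a1 at 0.876-fold, Arc at 0.807-fold, Bdnf at 0.888-fold and Homer1 at 0.836-fold. Glucocorticoid-responsive genes stood at -0.15 relative to all genes (percentile 0.01, 4 of 23 higher, below 0 in 14 of 14 regions before that subtraction), with Plin4 2.05-fold lower (1.69 to 2.41) and the metallothionein gene Mt2 1.57-fold lower (1.53 to 1.61). Heat shock and unfolded protein response genes stood at 0.25 relative to all genes (percentile 100, 20 of 23 higher), with Hspa1b at 1.48-fold (1.20 to 1.81) and Sdf2l1 at 1.47-fold (1.32 to 1.62). Mitochondrial transcripts made up 12.4% of the UMIs against 8.65% in the same comparison, and nuclear-retained transcripts stood at -0.39, endothelium at -0.17 and blood at 3.17 relative to all genes. The state of the tissue and RNA is not separated from behaviour for any list in this comparison. Neuropeptide and receptor genes stood at -0.19 (percentile 0.01), with Calca 5.88-fold lower (3.59 to 6.62), and Hox genes of groups 4 and 5 had a median log2 fold of -1.23 (1 of 7 higher). Ion channel genes stood at -0.07 (percentile 0.27), with Kcnma1 1.51-fold lower (1.37 to 1.66) and Cacna1a 1.41-fold lower (1.32 to 1.49), and presynaptic vesicle genes at -0.05 (percentile 0.38), with Cplx2 1.38-fold lower (1.29 to 1.47). Reactive glia genes stood at 0.15 (percentile 98.2, 10 of 19 higher), with Cd68 at 0.689-fold (0.516 to 1.01) and Gbp2 at 0.676-fold (0.492 to 1.06). Of 15 settings, these lists lay outside the central range in 15 for heat shock, 14 for neuropeptides, 13 each for immediate early, glucocorticoid and ion channel genes and 11 for presynaptic genes. Reactive glia genes did so in 8 only, with a lowest percentile of 19.1.

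**Figure D4:**
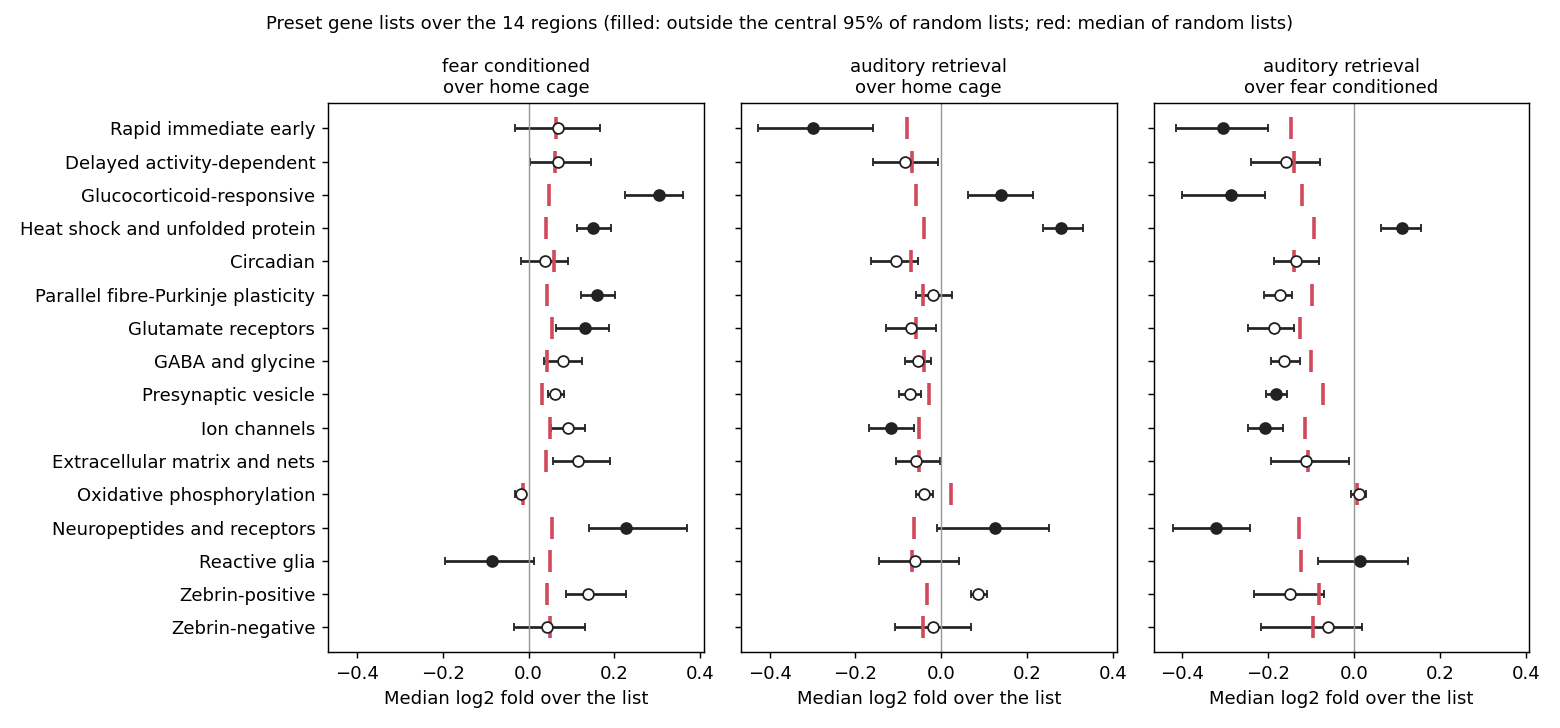
Median log2 fold of 16 preset gene lists (y) over the 14 regions in the 3 comparisons (panels), with 95% counting intervals as bars and the median of matched random lists in red; filled points lie outside the central 95% of random lists. Glucocorticoid-responsive genes stand at 0.30 for fear conditioned over home cage and heat shock genes at 0.28 for auditory retrieval over home cage, while extracellular matrix genes change sign with TMM scaling in the 2 comparisons of the auditory retrieval section.

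Relative to all genes, the lists inside the central range stood at -0.02 for delayed activity-dependent genes, 0.00 for circadian genes, -0.04 for parallel fibre to Purkinje cell genes, -0.05 for glutamate receptors and -0.03 for GABA and glycine genes. They stood at 0.02 for extracellular matrix genes, 0.15 for oxidative phosphorylation genes, -0.01 for zebrin-positive genes and 0.08 for zebrin-negative genes, whose median before the subtraction was -0.06, and 0.06 with TMM scaling. Outside it were blood transcripts at 3.17 (percentile 100), meninges at 0.18 (percentile 99.6, with a mean log2 fold of -0.04 against a median of 0.04), endothelium at -0.17 (percentile 0.15), microglia at -0.18 (percentile 0.16), interneurons and Golgi cells at -0.09 (percentile 1.92) and nuclear-retained transcripts at -0.39 (percentile 0.01). The other marker lists stood between -0.10 for forebrain and midbrain neurons and 0.05 for unipolar brush cells. Among these were 0.01 for the granule layer, 0.04 for Purkinje and molecular layer, 0.01 for white matter, 0.02 for deep nuclei and brainstem neurons, 0.01 for Bergmann glia and astrocytes, 0.03 for choroid plexus, -0.01 for ependyma and -0.08 for oligodendrocyte precursors. Relative to random lists matched on expression instead, oxidative phosphorylation genes stood at 0.00, white matter at -0.10, Purkinje and molecular layer at -0.05 and zebrin-positive genes at -0.07. By the size rule 36 genes were higher and 214 lower, against 88 and 76 with TMM scaling and 61 and 109 with totals that left out mitochondrial, haemoglobin and ribosomal protein genes. The share of higher genes was therefore 14.4%, 53.7% or 35.9%. Slc15a2 was 2.09-fold lower over all regions (1.81 to 2.36) and the synaptic scaffold gene Shank3 2.52-fold lower (2.15 to 2.86).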

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

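Thinning of the spots was set before the data were examined. Its use as a test of depth, revised once after a first run that gave the same verdict, and the tests on other regions, deep nuclei markers and Hox genes were chosen after the results they measure had been seen. Fos and Egr1 went opposite ways in 2 regions under the same comparison, with separate CPM intervals in both regions. The difference between regions itself was not tested, because each group had 1 section. For fear conditioned against home cage, the Fos log2 fold was 3.54 in the Spp1/Cd24a region and -1.22 in the Pcp2/Rgs8 region. For auditory retrieval against fear conditioned, it was 0.82 in the Pcp2/Rgs8 region and -1.04 in the Tnfaip6/Ppp1r14a region. The Egr1 log2 fold for auditory retrieval against home cage was 1.755 in the Spp1/Cd24a region and -1.20 in the Pcp2/Rgs8 region.

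Fos, Junb and Egr1 were higher in the Spp1/Cd24a region of both behaviour sections than of the home cage section. For a difference in depth, their counts were summed over spots thinned to 2000 UMIs. These sums were 77 in fear conditioned and 40 in auditory retrieval against 10 in home cage. The lower log2 fold was 2.465 (1.44 to 3.63), and the lowest single-gene value was 1.38 for Egr1 (8 counts against 4). Thinning keeps the expected proportions of genes within each spot, so it tests only whether deep spots outweighed shallow ones. The difference did not rest on such weights, and other effects of depth stay open. Against a section-wide shift, Fos had a log2 fold of 1 or more in at most 2 of the 13 other regions. That count covers Fos alone. Junb was higher than home cage in 13 of 14 regions for fear conditioned and 10 of 14 for retrieval, and Egr1 in 9 and 4. A wider rise of Junb thus stays open. For fewer deep nuclei neurons in the home cage spots, the medians of their 16 markers were -0.0920 (-0.14 to -0.04) and -0.0305 (-0.10 to 0.05). These medians cannot decide it. Spots were grouped by expression scaled within each section, and 5 such markers are among the region's top 50 genes. Another level along the brain's axis in the home cage section cannot be told apart from the groups with 1 section each, as Hox genes of paralog groups 4 and 5 had a median log2 fold of 1.43 for fear conditioned and 0.175 (-0.11 to 0.50) for auditory retrieval. Differences between mice, and the tone, shock and handling of the behaviour groups, stay open and untested.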

How the results depend on the processing

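No paired analysis was possible because each group had 1 section and no result came from a test. Restriction to the 6 cerebellar regions was chosen after seeing the data. In the Spp1/Cd24a region, Fos, Junb and Egr1 stayed higher than in home cage under the 12 settings that kept the region. Their log2 folds were 2.95 to 3.98, 2.52 to 4.08 and 1.77 to 2.79 for fear conditioned, and 2.43 to 3.21, 1.75 to 3.40 and 1.26 to 2.16 for auditory retrieval. Elsewhere, 473 of 630 values of other preset lists, 428 of 453 of immediate early genes in 1 region, 76 of 144 shares of spots and 2861 of 3200 single-gene values stayed within the original counting interval. The left and right sides of a section differed by a median absolute log2 fold of 0.0811 (home cage), 0.113 (fear conditioned) and 0.0977 (auditory retrieval). The same array sides of different sections, which need not be the same anatomical side, differed by more in most cases: by 0.112 and 0.134 for fear conditioned against home cage, 0.120 and 0.124 for retrieval against home cage, and 0.183 and 0.193 for retrieval against fear conditioned. Except for the stricter size rules, the cause was not tested.

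The median of the rapid immediate early list for fear conditioned against home cage, 0.07, was 0.21 on the left and 0.24 on the right side. Retrieval against home cage, -0.30, gave -0.0258 with every spot over tissue, -0.13 at Leiden resolution 1.5, -0.15 with regions by marker score, -0.15 on the right and -0.14 with 2 counts added. Retrieval against fear conditioned, -0.31, gave -0.18 with every spot, -0.15 with TMM, -0.48 on the left and -0.48 on the right. The share of regions with a list median above 0 was 57.1%, 14.3% and 7.14% in the 3 comparisons. It was 16.7% in the first in cerebellar regions, and 38.5% in the second by marker score and 38.5% over thinned spots. In the third it was 0% with 1000 UMIs per spot, 14.3% with every spot, 0% by marker score, 15.4% over thinned spots, 28.6% on the left and 16.7% in cerebellar regions.

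A 2-fold rule or 200 counts lowers gene counts by construction. In fear conditioned against home cage, 86 higher became 29 (2-fold) and 56 (200 counts). The 53 lower became 13 (2-fold), 31 (200 counts), 22 (thinned), 14 (left) and 28 (right). In retrieval against home cage, 41 higher became 22 (2-fold) and 26 (200 counts), and 109 lower became 18 (2-fold), 56 (200 counts), 57 (every spot) and 59 (TMM). In retrieval against fear conditioned, 36 higher became 88 (TMM), 61 (totals without mitochondrial, haemoglobin and ribosomal protein genes), 66 (marker score), 19 (left) and 16 (2-fold). The 214 lower became 126 (every spot), 76 (TMM), 109 (those totals) and 36 (2-fold). Preset lists outside the central range fell from 5 to 3 with every spot in retrieval against home cage, and from 7 to 4 over thinned spots in retrieval against fear conditioned.

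Some log2 values whose interval excluded 0 changed sign. In fear conditioned against home cage, the lists among them were presynaptic vesicle (-0.00342 with TMM, -0.00659 in cerebellar regions), ion channels (-0.00109 on the right) and zebrin-positive genes (-0.0376 on the left). Among genes they were Egr1 over all regions (-0.13 on the right, -0.0149 in cerebellar regions) and Uts2b in Calca/Tac1 (-1.25 at resolution 1.5). On the left they were Myl9 in Kit/Sla (0.000475) and Coa5 in Cdr1os/Prr18 (0.525).

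In retrieval against home cage, the lists were glucocorticoid-responsive (-0.0892 with every spot), glutamate receptors (0.00580 in cerebellar regions), oxidative phosphorylation (0.0384 with TMM, 0.0247 in cerebellar regions), GABA and glycine (0.00320 with TMM), extracellular matrix (0.0213 with TMM) and immediate early genes in Myoc/Gfap (0.19 over thinned spots). The genes were Gal in Calca/Tac1 (-0.26 at resolution 1.5) and Dlk1 in Ttr/Kl (-0.27 on the left). Over thinned spots they were Klhl32 in Tnfaip6/Ppp1r14a (-0.0266) and Tafa1 (-0.12) and Ak5 (0.33) in Tnnt1/Sln.

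In retrieval against fear conditioned, the lists were extracellular matrix (0.0259 with TMM) and zebrin-positive genes (0.0135 on the left). The genes were Ccn2 in Kit/Sla (0.0468 with every spot) and Cbln1 in Cdr1os/Prr18 (0.39 on the left). On the right they were Arc over all regions (0.11), Mgp in Myoc/Gfap (-0.55) and Bc1 in Tnnt1/Sln (-0.24). Preset lists whose interval included 0 also changed sign with TMM. These were circadian (-0.02) and zebrin-negative genes (-0.01) in the first comparison, parallel fibre to Purkinje cell (0.05), reactive glia (0.06) and zebrin-negative genes (0.05) in the second, and zebrin-negative genes (0.06) in the third.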

Other observations

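Thinned spots and TMM factors were set before the data were examined. Their use as tests here, and the tests on Hox genes and on glia and vessel markers, were chosen after the results they measure had been seen. The interval bounds of 3 tests were tightened after a first run without a change of verdict, and the genes of this paragraph were chosen after their values were seen. In the Calca/Tac1 region, the 3 highest genes of the fear conditioned section relative to home cage by the naming rule were Uts2b, Npy and Dbh. Uts2b, a urotensin-related peptide gene, was 9.77-fold higher, Npy 4.18-fold and Dbh, which encodes the enzyme that makes noradrenaline, 3.43-fold. With finer regions the log2 fold of Uts2b turned to -1.25. In the Ttr/Kl region, led by choroid plexus genes, the phosphatase gene Dusp1 stood at 161 CPM in the fear conditioned section against 98.3 CPM in home cage and 63.0 CPM in auditory retrieval. Egr1 in that region stood at 24.8, 15.2 and 4.69 CPM in the same order. The metallothionein gene Mt1 averaged 4355 CPM over all regions in the fear conditioned section, 3795 CPM in home cage and 3021 CPM in auditory retrieval.

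Hox genes, which mark position along the hindbrain, differed between sections: the 7 genes of paralog groups 4 and 5 had a median log2 fold of 1.43 (1.12 to 1.75) in fear conditioned against home cage, with 7 of 7 higher and 1050 counts against 400. The 7 genes of groups 1 to 3 had a median of -0.08 (-0.37 to 0.24). Over thinned spots the median of groups 4 and 5 was 0.929 (0.56 to 1.28). The difference thus did not rest on the weight of deep spots alone, and thinning leaves other effects of depth open. A more caudal level of the brainstem in the fear conditioned section is a candidate explanation, with a difference of the medians of 1.51 (1.07 to 1.96). It cannot be told apart from the group with 1 section each, and high values of several of these genes had prompted it, so the same values cannot support it.

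The glucocorticoid-responsive list was higher in the fear conditioned section than in home cage. Its median over thinned spots was 0.295 (0.22 to 0.39), so it did not rest on the weight of deep spots. Thinning leaves other effects of depth open. Against a shift from scaling, the median was 0.252 (0.17 to 0.31) under TMM factors. White matter markers had a median of -0.00150 (-0.02 to 0.02), but a summed log2 fold of 0.12, and endothelium markers 0.0748 (0.02 to 0.14). More glia or vessel cells as a whole cannot be told apart from the group, since the astrocyte and Bergmann glia markers had a median of 0.130 (0.09 to 0.17), between the bounds set for and against. A response to shock or handling and differences between mice stay open and untested.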
